A study of Mus musculus with 8 samples.

How the data were processed

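RNA was taken from the inguinal white fat of 8 mice, 4 knockouts and 4 LoxP controls, amplified as cDNA with the Ovation RNA Amp System V and hybridised to Affymetrix mouse arrays, per the labels' protocols. The deposited table holds log2 values per probe set, made by RMA with the affy package, per the submitters' processing notes; versions are not given in the sources used here. RMA corrects background, quantile-normalizes the arrays and summarises the probes of each probe set. The values lie between 3.17 and 13.5, with a median of 5.87 to 5.94 on each array. RMA gives no call of presence, so a level near the lower end cannot be told from background. No genome build is named, so no coordinates are given.

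The table holds 45141 probe sets. Of these, 28898 are paired with 1 gene symbol in the platform annotation, 551 with several, and 15692 are not listed there. For 28689 of the single-symbol probe sets the Entrez ID was found in the reference table, which changed 0 symbols, and the annotation's symbol was kept for the other 209. Each of the 17097 genes was represented by the probe set with the highest mean over all arrays; 7180 genes had more than 1. Probe sets with several symbols or none were not named, and 0 of them passed an adjusted p under 0.05.

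Groups were taken from the genotype labels and litters from the litter labels. Replicate numbers follow the order of the samples and pair nothing. The highest correlation between any 2 arrays was 0.995, and no array was counted as a repeat of another. Knockouts were compared with controls by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with neither trend nor robust fitting), with genotype as the only term, no filter on low values, and Benjamini-Hochberg adjustment over 17097 genes at a threshold of 0.05. Differences are knockout minus control on the log2 scale. Litter was left out of the model because litter Cx33 holds no knockout, so that a litter block removes its 2 controls from the contrast. The value with litter as a block and the difference within each litter that holds both genotypes are given beside each list that passed. Each such litter has 1 control, so a difference within 1 litter carries no test of its own. The consensus correlation between arrays of a litter was 0.177.

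Gene lists were fixed from textbook knowledge before the data were examined: 38 lists of pathway genes and markers of cell types that a dissected depot can hold, with 807 of 905 memberships measured. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 38 lists. Camera compares the moderated statistics of a list with those of all other genes, so its direction can differ from the sign of the mean log2 difference. The list mean of an array is the mean of its members, each centred over the 8 arrays. Some lists share members: 7 of the 16 adipocyte markers and 5 of the 22 insulin signalling genes are also on another list.

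The genes named were chosen by a rule fixed before the data were examined. Trp53inp2 came first; then, per direction, up to 12 genes of largest difference past the threshold with non-overlapping groups, or, where fewer passed, the genes of smallest p up to 8, by value only. Up to 4 members of smallest p could be named per list, and 13 further genes whatever their values, of which Sqstm1 and Map1lc3b had no single-symbol probe set. Genes named outside this rule are marked as chosen after their values were seen.

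The procedure was tested on simulated data with the means and spread of these 17097 genes and independent errors. Of 50 genes changed per fold size, it recovered 64% at 1.5-fold, 84% at 2-fold, 96% at 4-fold and 98% at 8-fold, and 10 of the 194 genes it called were unchanged. The 194 also include members of a list that was shifted to test camera. The real arrays share structure, such as that of litter Cx33, that independent errors lack. These rates may therefore overstate recovery in the real arrays, and they do not show that undetected changes are few.

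Alternatives fixed beforehand were a filter to the upper 50% of genes by mean, the mean of all probe sets of a gene, eBayes with trend and robust fitting, median centring, quantile normalization, array weights, litter as a fixed or random block, the 2 litters with both genotypes alone, each replicate left out, all probe sets, an unadjusted threshold with at least 1.5-fold, an estimated correlation for camera, and fry. Another 3 were added after the data were seen: the B cell list mean as a covariate, the B cell and skeletal muscle list means as covariates, and a fit without controls 1, 2 and 4, which leaves 1 control that is assumed to vary like the knockouts. A value was counted as reversed only where it passed the threshold in the original or the alternative fit and changed direction.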

Results

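Gene expression was measured in inguinal white adipose tissue, a subcutaneous fat depot that surrounds a lymph node and lies against skin and muscle, from 8 male C57BL/6J mice aged 4 months. All mice carried loxP sites around TP53INP2 (mouse gene Trp53inp2), which encodes a protein known for a role in autophagy, and all ate a tamoxifen diet from 2 months of age. The 4 knockout mice also carried a ubiquitous tamoxifen-inducible Cre recombinase, and the 4 control mice, called LoxP controls, did not. Whether the lymph node was removed before extraction is not given in the sources used here. The labels place the mice in 3 litters. Litter Cx33 held controls 1 and 2 and no knockout, litter Cx34 held knockouts 1 and 2 with control 3, and litter Cx28 held knockouts 3 and 4 with control 4. Each mouse gave 1 array, and 17097 genes had a probe set with a single gene symbol. The comparison asks which transcripts of this fat depot differ when TP53INP2 is lost in the adult, and the number of arrays limits its precision. Every mouse that carried Cre was a knockout, so effects of Cre itself cannot be told apart from those of losing TP53INP2.

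The targeted gene, Trp53inp2, had a lower value in each of the 4 knockouts than in any control. Its mean log2 value was 9.85 ± 0.19 (SD, n = 4) in knockouts and 10.88 ± 0.26 (SD, n = 4) in controls, a difference of -1.03 with a 95% interval of -1.36 to -0.70. The knockouts therefore held 49.0% of the control signal, a 2.04-fold difference. Knockout values ran from 9.59 to 10.03 and control values from 10.64 to 11.17. The difference was -1.26 within litter Cx34, -1.23 within litter Cx28 and -1.25 with litter as a block. An exact two-sided permutation test of the means over 70 arrangements gave p = 0.0286, which is the smallest p this design allows, and limma gave an adjusted p of 0.22 over all genes. The 70 arrangements exchange mice across litters, so that p takes no account of litter. The gene has 1 probe set here, and the probe table does not place it relative to the deleted exons.

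**Figure D1:**
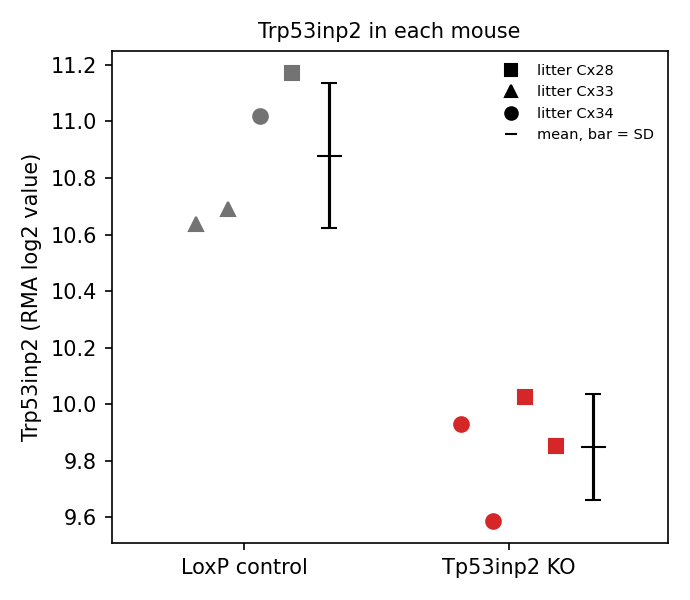
Log2 value of Trp53inp2 (vertical axis) in each mouse by genotype (horizontal axis), with the marker shape giving the litter and the bar giving the mean ± SD of 4 mice. The 4 knockouts lie between 9.59 and 10.03, all below the controls at 10.64 to 11.17.

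The arrays separated more by litter Cx33 than by genotype. The first principal component held 64.9% of the variance, and controls 1 and 2 scored -48.0 and -42.6 on it, control 4 scored -7.65, control 3 scored 12.7 and the knockouts scored 12.7 to 31.6. Control 4, of litter Cx28, thus lay on the side of controls 1 and 2. The B cell markers described below set these arrays apart in the same order, so this axis cannot be assigned to litter alone. Across genes, the 2 Cx33 arrays correlated with each other at 0.992 and with the other 6 arrays at 0.953 to 0.986, while those 6 correlated with one another at 0.980 to 0.995. Genes are not independent replicates in these correlations. Differences between 3' and 5' control probe sets for actin were alike on all arrays, at -0.60 to -0.50.

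The genes of smallest p with lower values in knockouts included immunoglobulin and matrix transcripts. The immunoglobulin light chain gene Igk-V21 differed by -2.82 (SE 0.34), Trp53inp2 by -1.03, the matrix gene Postn (periostin) by -0.93 (SE 0.14) and the heavy chain gene Ighv6-6 by -0.89 (SE 0.13). Apoc1, an apolipoprotein gene, differed by -1.37 (SE 0.22), the histone methyltransferase gene Kmt5c by -0.57, the phosphatase gene Ptprf by -0.36 and Cd80, a costimulatory molecule of antigen-presenting cells, by -0.36. The genes of smallest p with higher values included Gpt2, which encodes mitochondrial alanine aminotransferase, at 0.69 (SE 0.10), and Oxct1, an enzyme of ketone body use, at 0.32 (SE 0.05). Muscle genes were also among them, with the fast myosin Myh2 at 1.92 (SE 0.30), the muscle mitochondrial creatine kinase Ckmt2 at 2.02 (SE 0.33) and Aqp4, a water channel of fast fibres, at 1.54 (SE 0.27). The remaining 3 were Lonrf1 at 0.86, Syt12 at 0.68 and Hoxa13 at 0.24. In each of these genes the 4 knockouts lay on 1 side of the 4 controls. That alone fixes the same sign within litters Cx34 and Cx28. Limma's adjusted p was 0.22 for each, so none was called with all 8 arrays. Without control 3, Igk-V21 passed in limma at -3.16 (adjusted p = 0.011). Control 3 had the lowest Igk-V21 value of the controls, at 7.23 against 8.32 to 8.80. Leaving it out therefore enlarges the difference by itself, and that call adds no support.

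Of 17097 genes, 0 passed an adjusted p under 0.05 in limma. At an unadjusted p under 0.05 there were 3368 genes, 1690 higher and 1678 lower in knockouts, where chance alone would give 855 on average. With each array centred on its median, that split was 2256 higher and 1403 lower. The 2 groups did not overlap for 1562 of the 17097 genes. Chance gives a share of 2.86% for 4 against 4 if all arrays are exchangeable. The 2 arrays of litter Cx33, both controls, stand apart, so that share is only a guide. With litter as a block, 0 genes passed the adjusted threshold and 1271 the unadjusted one. Of the 168 genes that the naming rule covers, 92 had a difference over 1.5 times smaller with the block or of the other sign (4 of them), so the values of single genes below, given without the block, often lean on the controls of litter Cx33. Without control 3, whose lymphoid markers lay in the knockout range, 42 genes passed the adjusted threshold, 2 higher and 40 lower, and 11 of them are on the B cell, T cell and lymph node lists. That count understates the lymphoid share. The immunoglobulin genes Igk-V21, Igkv6-15, Iglv1 and Jchain and the lymphocyte genes Btla and Tnfrsf13c also passed but are not on these lists. All of them but Igk-V21 were chosen after their values were seen.

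Among 38 gene lists fixed before the data were examined, 16 passed an adjusted p under 0.05 in limma's camera test with a preset correlation, 7 higher and 9 lower in knockouts. None of the 16 passed with an estimated correlation. With the B cell list mean as a covariate, chosen after the data were seen, 4 of the other 15 passed in the same direction (macrophages, lysosome, cholesterol synthesis and oxidative phosphorylation). Among controls, only control 3 had a B cell list mean in the knockout range, so the genotype difference in that fit leans on control 3. The B cell and the T and NK cell lists had the smallest p. All 18 measured B cell markers had lower values in knockouts, 0 of them past the threshold over all genes and 17 adjusted over the list alone, with a mean log2 difference of -2.02 (adjusted p = 4.6e-10, and adjusted p = 0.76 with an estimated correlation). Of 20 T and NK cell markers, 19 were lower, 8 of them past the threshold adjusted over the list alone, with a mean of -1.24 (adjusted p = 2.2e-08, and adjusted p = 0.76 with an estimated correlation). Lymph node stroma markers, which include transcripts of high endothelial venules, had a mean of -0.94 with 7 of 8 lower and 0 past the threshold adjusted over the list alone (adjusted p = 0.0028, and adjusted p = 0.76 with an estimated correlation). As examples, Cd37, a leukocyte tetraspanin, differed by -2.09 (SE 0.51), Cd79b of the B cell receptor by -2.32 (SE 0.70), Cd3e of the T cell receptor complex by -2.89 (SE 0.93), and the venule mucin gene Glycam1 by -2.62 (SE 0.84). These lists did not divide the mice by genotype. The centred B cell list mean was 2.23 in control 1, 2.13 in control 2 and 0.63 in control 4, while control 3, at -0.96, lay among the knockouts at -1.06 to -0.93. The B cell list therefore differed by -0.04 within litter Cx34 and by -1.66 within litter Cx28, and by -0.85 with litter as a block. The corresponding values were 0.03, -1.02 and -0.49 for T and NK cells and -0.14, -0.55 and -0.34 for lymph node stroma.

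**Figure D2:**
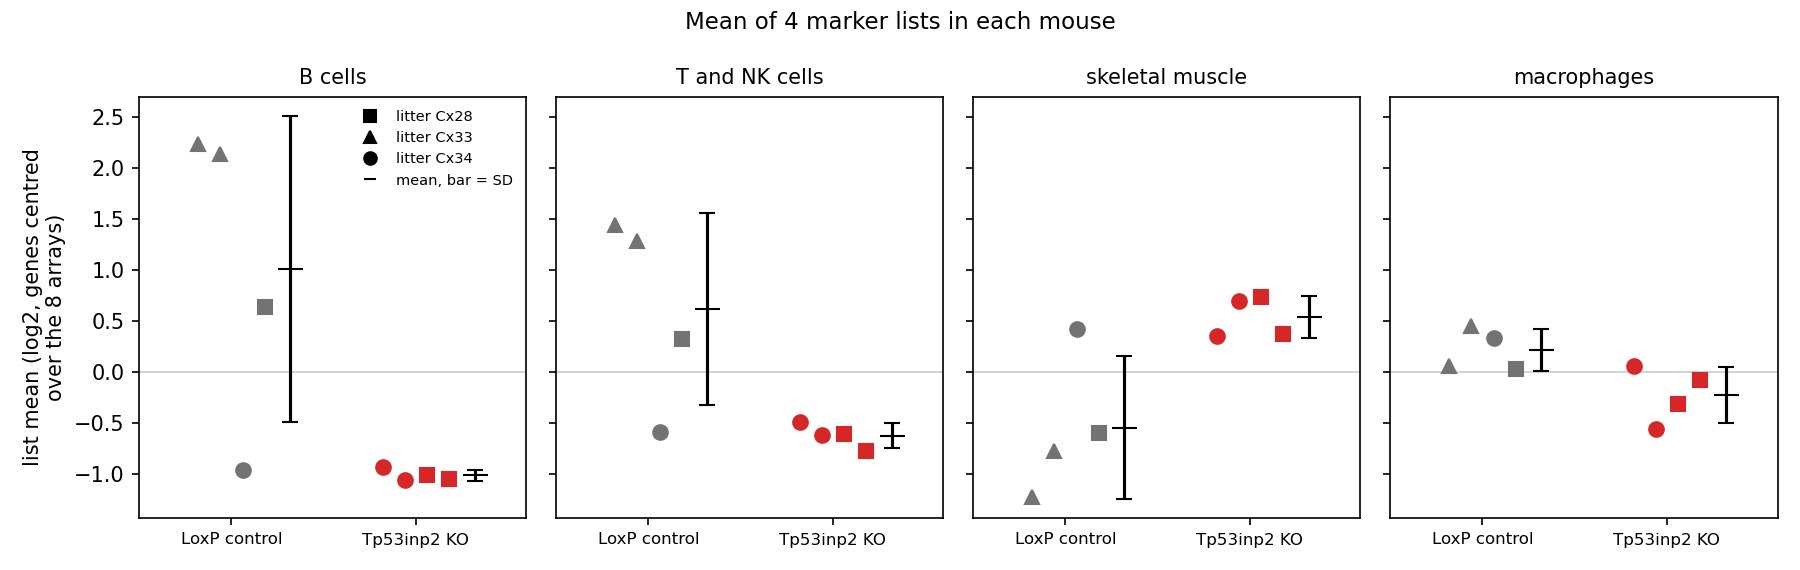
Mean of 4 marker lists in each mouse (vertical axis, log2 with each gene centred over the 8 arrays) by genotype (horizontal axis), with the marker shape giving the litter and the bar giving the mean ± SD of 4 mice. For B cells, controls 1, 2 and 4 lie at 2.23, 2.13 and 0.63, and control 3, at -0.96, lies with the knockouts.

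Macrophage markers were lower in knockouts in 23 of 24 genes, 2 of them past the threshold adjusted over the list alone, with a mean of -0.44 (adjusted p = 3.3e-06, and adjusted p = 0.76 with an estimated correlation). Lyz2, the macrophage lysozyme, differed by -0.59 (SE 0.14), Mpeg1 (perforin-2) by -1.07 (SE 0.26) and the growth factor receptor Csf1r by -0.47 (SE 0.16). This list was lower within both litters, by -0.58 in Cx34 and -0.23 in Cx28, and had a mean of -0.40 with litter as a block (adjusted p = 3.0e-07, and adjusted p = 0.92 with an estimated correlation). It did not divide the mice by genotype either. The centred macrophage mean was 0.060, 0.45, 0.34 and 0.033 in controls 1 to 4. It was 0.065, -0.56, -0.31 and -0.076 in knockouts 1 to 4. The lysosome list had a mean of -0.09 with 22 of 35 genes lower and 1 past the threshold adjusted over the list alone (adjusted p = 0.020, and adjusted p = 0.79 with an estimated correlation). Its leading members were the hydrolase genes Gusb at -0.35 (SE 0.07), Ctss at -0.63 (SE 0.17), Man2b1 at -0.35 (SE 0.10) and Ctsh at -0.81 (SE 0.23). The lysosome mean was -0.23 within Cx34, -0.03 within Cx28 and -0.13 with the block, and its call was lost without control 3 (mean of -0.044), knockout 2 or knockout 3 (-0.059), in the upper 50% of genes by mean (adjusted p = 0.055) and with array weights (adjusted p = 0.053).

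Another 4 lists were lower, and each had its highest value in a control of litter Cx33, where the B cell markers were also highest. Cell cycle genes had a mean of -0.35 with 27 of 29 lower (adjusted p = 4.3e-07, and adjusted p = 0.76 with an estimated correlation), among them the replication helicase gene Mcm5 at -1.08 (SE 0.37) and E2f1 at -0.29 (SE 0.09). Neutrophil and mast cell markers had a mean of -0.56 with 15 of 17 lower (adjusted p = 0.0015, and adjusted p = 0.79 with an estimated correlation), with the mast cell protease genes Mcpt4 at -1.18 (SE 0.44) and Cpa3 at -1.03 (SE 0.45). Interferon response genes had a mean of -0.25 with 18 of 20 lower (adjusted p = 0.0018, and adjusted p = 0.79 with an estimated correlation), and Irf1 differed by -0.38 (SE 0.10). Ribosome biogenesis genes had a mean of -0.08 with 22 of 29 lower (adjusted p = 0.025, and adjusted p = 0.79 with an estimated correlation). There Polr1c, a subunit of RNA polymerases I and III, differed by -0.31, the nucleolar methyltransferase gene Fbl by -0.33 and the polymerase I factor gene Rrn3 by 0.43. In these lists 0 members passed the threshold adjusted over the list alone. With litter as a block the means were -0.05, -0.12, -0.08 and 0.03, with adjusted p of 0.10, 0.45, 0.23 and 0.59, so all 4 calls were lost. Within Cx34 they were 0.02, -0.23, 0.03 and 0.09, and within Cx28 they were -0.12, -0.01, -0.18 and -0.02. The neutrophil and mast cell and interferon calls were also lost without control 2, at means of -0.18 and -0.09, where control 2 alone had a neutrophil and mast cell value of 1.44 against -0.28 to 0.02 in the other controls. Without control 3 the interferon mean was -0.38 and the ribosome biogenesis mean -0.16. The ribosome biogenesis call was lost without any 1 of controls 1, 2 and 4 (means of -0.034, -0.046 and -0.070) or knockouts 1 and 2 (-0.040 and -0.065), in the upper 50% of genes (adjusted p = 0.070) and with litter as a random block (adjusted p = 0.11).

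Skeletal muscle genes had higher values in knockouts in all 23 measured members, with a mean of 1.08 and 1 member past the threshold adjusted over the list alone (adjusted p = 8.5e-08, and adjusted p = 0.76 with an estimated correlation). Myoglobin (Mb) differed by 0.95 (SE 0.24), the fast troponin gene Tnnt3 by 1.08 (SE 0.35) and the slow and cardiac troponin gene Tnnc1 by 2.02 (SE 0.68). The mean list value per mouse ran opposite to the B cell list, at -1.23 in control 1, -0.77 in control 2 and -0.59 in control 4, with control 3 at 0.42 and the knockouts at 0.36 to 0.73. The difference was 0.11 within Cx34, 1.15 within Cx28 and 0.63 with litter as a block. Smooth muscle and pericyte genes were higher in 12 of 13 members, with a mean of 0.34 and 0 members past the threshold adjusted over the list alone (adjusted p = 0.0063, and adjusted p = 0.76 with an estimated correlation). Smooth muscle actin (Acta2) differed by 0.43 (SE 0.13) and Synpo2, an actin-binding protein gene also active in skeletal muscle, by 1.32 (SE 0.39). That list mean was 0.15 within Cx34, 0.19 within Cx28 and 0.17 with the block.

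Cholesterol synthesis genes were higher in 16 of 19 members with a mean of 0.30 (adjusted p = 0.0028, and adjusted p = 0.79 with an estimated correlation). Hsd17b7 differed by 0.55 (SE 0.15), Fdps by 0.65 (SE 0.21) and Lss by 0.72 (SE 0.25), all enzymes of the pathway. The list mean was 0.52 within Cx34 but -0.10 within Cx28, and 0.21 with the block, and the call was lost without control 3. Adipocyte markers were higher in 14 of 16 members with a mean of 0.19 (adjusted p = 0.024, and adjusted p = 0.79 with an estimated correlation). Lep (leptin) differed by 0.85 (SE 0.31), Pparg, the central adipogenic nuclear receptor, by 0.28 (SE 0.12), and Adipoq (adiponectin) by 0.06 (SE 0.05). With the block Lep differed by 0.29 and Pparg by 0.25, and within Cx28 by 0.07 and -0.02. Within Cx34 that mean was 0.16, within Cx28 it was -0.01 and with the block it was 0.08 (adjusted p = 0.26), so the call was lost. It was also lost without control 2 (mean of 0.13), knockout 1 or knockout 4, and with quantile normalization (adjusted p = 0.079). Insulin signalling genes were higher in 19 of 22 members with a mean of 0.17 (adjusted p = 0.018, and adjusted p = 0.76 with an estimated correlation), with Irs1, the insulin receptor substrate, at 0.37 (SE 0.12). The adaptor gene Grb14, at 1.29 (SE 0.47), and the phosphatase gene Ptpn1, at -0.56 (SE 0.19), encode known inhibitors of the receptor. With the block these 3 differed by 0.18, 0.39 and -0.20. The insulin signalling mean was 0.10 within Cx34, 0.07 within Cx28 and 0.09 with the block, and its call was lost without control 2. Oxidative phosphorylation genes were higher in 37 of 43 members with a mean of 0.08 (adjusted p = 0.016, and adjusted p = 0.79 with an estimated correlation), for example Atp5c1 at 0.14 and Ndufa6 at 0.19. That mean was 0.14 within Cx34, 0.07 within Cx28 and 0.11 with the block, and the call was lost without control 3 (mean of 0.046) or knockout 3 (0.030), with quantile normalization (adjusted p = 0.11) and with array weights (adjusted p = 0.23). Circadian clock genes were higher in 14 of 16 members with a mean of 0.29 (adjusted p = 0.015, and adjusted p = 0.76 with an estimated correlation), with Per2 at 0.36 and Tef at 0.52. With the block the circadian mean was 0.11 (adjusted p = 0.28), so the call was lost, and it was 0.16 within Cx34 and 0.07 within Cx28. In these 5 lists 0 members passed the threshold adjusted over the list alone, and in each but oxidative phosphorylation, controls 1 and 2, with the highest lymphoid markers, lay below all 4 knockouts.

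**Figure D3:**
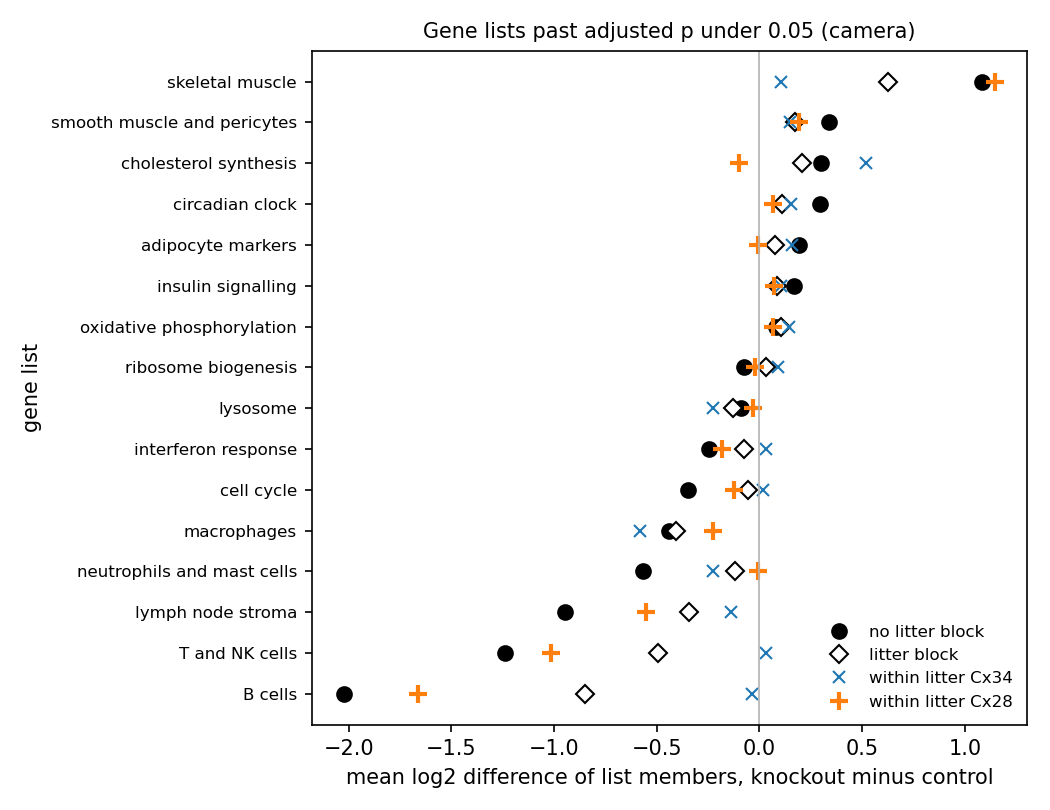
Mean log2 difference, knockout minus control, of the members of the 16 gene lists past the threshold (vertical axis lists, horizontal axis log2 difference), without a litter block, with it, and within each litter that held both genotypes. The B cell list lies at -2.02 without the block and at -0.85 with it, and the macrophage list at -0.44 and -0.40.

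Adipose progenitor and extracellular matrix genes missed the threshold without the block and passed it with litter as a block. Progenitor markers had a mean of -0.16 (adjusted p = 0.056), and -0.34 with the block (adjusted p = 6.1e-06, and adjusted p = 0.92 with an estimated correlation), with -0.47 within Cx34 and -0.21 within Cx28. Matrix genes had a mean of -0.14 (adjusted p = 0.056) with 1 of 30 members past the threshold adjusted over the list alone, and -0.29 with the block (adjusted p = 1.3e-05, and adjusted p = 0.93 with an estimated correlation), with -0.45 within Cx34 and -0.13 within Cx28. Control 3, which also held hair follicle transcripts, had the highest values of both lists, at 0.42 for progenitors and 0.39 for matrix genes, and without it their means were -0.042 and -0.033 (adjusted p = 0.56 for both). Without control 1 they were -0.27 and -0.26, without knockout 1 -0.24 and -0.20, and without knockout 2 -0.089 and -0.079. With the B cell covariate they were -0.49 (adjusted p = 1.6e-09) and -0.43 (adjusted p = 6.6e-10) by the preset correlation. That fit leans on control 3, the only control whose B cell list mean lay in the knockout range. Cd55, a surface marker of early progenitors, differed by -0.51 (SE 0.13), the matrix gene Tnc (tenascin C) by -0.50 (SE 0.12), Tgfb1 by -0.60 (SE 0.17) and the collagenase gene Mmp14 by -0.82 (SE 0.28). Lipogenesis genes had a mean of 0.22 (adjusted p = 0.055) and, with the block, 0.18 (adjusted p = 0.033, and adjusted p = 0.93 with an estimated correlation), with 0.52 within Cx34 and -0.15 within Cx28. Without control 3 the lipogenesis mean was 0.13 (adjusted p = 0.56), and without control 4 it was 0.33 (adjusted p = 0.00042). The lipogenic transcription factor gene Mlxipl differed by 0.47 (SE 0.18), and Fasn (fatty acid synthase) by 0.09 (SE 0.10).

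Autophagy genes, the pathway that TP53INP2 is known for, had higher values in 28 of 36 members with a mean of 0.09 (adjusted p = 0.056), with Epg5 at 0.22 (SE 0.05) and Becn1 at 0.14 (SE 0.06). With litter as a block the autophagy mean was 0.04 (adjusted p = 0.34), and with the B cell covariate it was 0.015 (adjusted p = 0.90). The list passed without knockout 1 (adjusted p = 0.048), without control 3 (adjusted p = 0.049), with array weights (adjusted p = 0.047) and with the mean of all probe sets (adjusted p = 0.0499). The Wnt lists, which bear on the beta-catenin signalling that restrains fat cell formation, did not pass. Wnt target genes were higher in 13 and lower in 9 of 22 members, with a mean of -0.04, a median of 0.04 and a camera direction down (adjusted p = 0.92), and Axin2 differed by 0.15 (SE 0.12). Their member Lef1 differed by -1.54 (SE 0.55) and followed the order of the B cell list. It stood at 7.03, 6.23 and 5.12 in controls 1, 2 and 4, 4.13 in control 3 and 4.02 to 4.12 in knockouts. Wnt pathway components had a mean of 0.06 (adjusted p = 0.36), with Ctnnb1 (beta-catenin) at 0.06 (SE 0.06) and its kinase Gsk3b at 0.25 (SE 0.09). That mean was of either sign across alternatives, at -0.10 with the block (adjusted p = 0.29), -0.018 without control 1, 0.031 without control 2 and 0.15 without control 3. With the B cell covariate, a fit that leans on control 3, it was -0.21 (adjusted p = 0.0014). Adipogenic transcription factors had a mean of 0.03 (adjusted p = 0.84), with Cebpa at 0.10 (SE 0.10). The paralogue Trp53inp1 differed by -0.49 (SE 0.18, adjusted p = 0.23), but by -0.17 (SE 0.09) with the block, -0.22 within Cx34 and -0.13 within Cx28. Its values were 9.87 and 9.68 in the controls of litter Cx33 and 9.13 in each of the other 2. Fabp4, the fatty acid binding protein of fat cells, differed by -0.13 (SE 0.13). The list of endosomal sorting genes, the MVB machinery, had a mean of 0.02 (adjusted p = 0.92).

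The other lists did not pass in camera with all 8 arrays either, and the alternatives given for them and for the autophagy and Wnt lists use the preset correlation. Brown and beige thermogenesis genes had a mean of -0.09 (adjusted p = 0.43), and Ucp1, the uncoupling protein, differed by -0.97 (SE 1.09). The thermogenesis mean was -0.24 without knockout 3, where it passed (adjusted p = 0.032), and -0.03 with the block (adjusted p = 0.77). It was -0.021 without knockout 4, -0.029 without knockout 1 and -0.044 without control 4. Fatty acid oxidation had a mean of -0.07 (adjusted p = 0.097), triglyceride synthesis and fatty acid uptake 0.07 (adjusted p = 0.39), lipolysis 0.02 (adjusted p = 0.39) and thyroid hormone responsive genes 0.05 (adjusted p = 0.35). The lipolysis mean changed sign when 1 array was left out, at -0.036 without knockout 4 and 0.10 without knockout 3. Knockout 3 alone was high for the thyroid list, at 0.36 against -0.10 to -0.08 in the other knockouts. Fatty acid oxidation passed without control 3 at -0.14 (adjusted p = 0.0071), without knockout 3 at -0.13 (adjusted p = 0.0075) and with array weights at -0.12 (adjusted p = 0.027), but with the block its mean was -0.020 (adjusted p = 0.56). The mean was also nearer 0 without knockout 1, at -0.021, and without control 4, at -0.043. With B cell and muscle covariates, triglyceride synthesis and lipolysis passed at 0.17 (adjusted p = 0.0095) and 0.19 (adjusted p = 0.0019). Inflammatory cytokines and chemokines had a mean of -0.21 and a median of -0.03 (adjusted p = 0.072), with 11 members higher and 15 lower. The p53 target genes had a mean of 0.03 and a median of 0.11 (adjusted p = 0.28), with 15 higher and 8 lower, and NRF2 targets a mean of 0.11 (adjusted p = 0.36). Ccl5 at -1.96 (SE 0.69), Ccl8 at -1.54 (SE 0.43) and the p53 target Pmaip1 at -1.65 (SE 0.51) were highest in the controls of litter Cx33. The inflammatory list passed without knockout 4 at -0.24 (adjusted p = 0.035) and with array weights at -0.29 (adjusted p = 0.038), but with the block its mean was -0.050 (adjusted p = 0.58). Immediate early genes had a mean of 0.08 (adjusted p = 0.63). ATF4 and unfolded protein response genes had a mean and a median of 0.03 and 0.02 with a camera direction down (adjusted p = 0.81). Among cell type markers, endothelial cells had a mean of 0.14 (adjusted p = 0.36), epithelium and mammary duct -0.36 (adjusted p = 0.35; -0.052 without control 1, the highest array), and erythrocytes 0.11 (adjusted p = 0.43). Endothelial cells passed without control 4 at 0.23 (adjusted p = 0.017), and their mean was -0.025 with the block. Schwann cells and nerve had a mean of -0.02 and a median of 0.05, with a camera direction up (adjusted p = 0.98). In the lists that missed the threshold, matrix genes apart, 0 members passed the threshold adjusted over the list alone.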

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

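The tests of lymph node tissue, lymphocyte content, dilution, muscle tissue and immunoglobulin source were chosen after the results were seen; the counts over other splits of the arrays were set down before they were run.

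Lymphoid lists were lower in knockouts, but in the B cell, T and NK cell and lymph node stroma lists, 3 of 3, controls 1 and 2 lay highest, control 4 next, and control 3 and the knockouts together below. That order is consistent with lymph node tissue in some dissections, but whether the node was removed before extraction is not given in the sources used here, and array levels do not show which markers fat itself expresses. The B cell markers Cd37 and Cd79a (the latter chosen after its values were seen) stood at 7.92 and 6.38 in knockouts against 10.01 and 9.26 in controls. Lower lymphocyte content in every knockout mouse stays open: the B cell list differed by -0.037 within litter Cx34, but that rests on control 3 alone, and by -1.66 within litter Cx28.

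Among the 35 splits of the 8 arrays into 4 and 4, 8 called as many lists as the 16 of the real one, with 19 as the highest of the others, so chance is not excluded for the number of lists; 7 of these 8 keep the 2 arrays of litter Cx33 on one side, a structure of the samples, and with litter as a block 13 lists passed. For genes at an unadjusted p under 0.05, 1 of 35 splits, the real one, reached 3368 against 3027 for the highest other. That is the smallest share that 35 splits can give, and it counts only if arrays of all litters are exchangeable. The 2 arrays of litter Cx33 stand apart from the others, so chance is not excluded for that number. The 3027 came from a split that keeps the 2 arrays of litter Cx33 together, as the real one does. Only 15 splits do so, too few for a share under 5%, so they do not separate genotype from that litter. For the adjusted threshold, all 35 splits had at least the 0 genes of the real one, with 1 as the highest other, so that count says nothing of chance.

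The skeletal muscle list was higher in knockouts and low in controls 1, 2 and 4. Dilution by lymphoid RNA would lower muscle and adipocyte transcripts in those controls alike, but the 2 list means differed by 0.89 (SE over members 0.11). In controls 1, 2 and 4 the muscle list stood at -1.23, -0.77 and -0.59, and the adipocyte list at -0.13, -0.29 and 0.07. These values argue against equal dilution as the whole source. The SE treats correlated genes of the same arrays as replicates, so it gives no spread between mice and no test. Muscle tissue in some dissections remains possible: control 3 had a list mean of 0.42, inside the knockout range of 0.36 to 0.73. Single genes did not all follow: 6 of the 23 members were higher in knockouts than in control 3 within litter Cx34, Myh2 by 1.79 and Tnnc1 by 1.97 among them. So were Ckmt2 by 1.14 and Aqp4 by 1.87, which are not on the list, and control 3 is 1 library, so muscle tissue as the source of these genes stays open. A change of muscle transcripts with genotype was not tested apart from the dissection.

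Some immunoglobulin transcripts were lower in knockouts than in control 3 as well. Of 17 such genes measured, 4 passed a filter on dim genes (a mean above the median gene), and 3 of these 4, Igk-V21, Igkj1 and Jchain (the last 2 chosen after their values were seen), were lower within both litters and had groups that did not overlap, while the other, a kappa variable gene, differed by 0.02 within litter Cx34. With lymph node tissue as the only source, the 4 genes that passed might follow the B cell list. The median difference of that list within litter Cx34 was near 0 with an SD of 0.28. The median of the 4 genes there was -0.64, and -2.73 within litter Cx28. One control library and 4 genes cannot exclude that source, so it and a lower plasma cell content in knockouts cannot be told apart.

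Within the 2 litters that hold both genotypes, the knockout difference itself was tested for a difference between litters by an interaction term in limma, which rests on 1 control per litter. Each lone control is assumed to vary like the knockouts, whose pairs within a litter give the spread. The interaction gave 0 genes at an adjusted p under 0.05 and 940 at an unadjusted p under 0.05, where chance alone would give 855 on average. It gave 17 lists by camera with the preset correlation, of which 0 passed with an estimated correlation. The values are the list mean in Cx28 minus that in Cx34. The lymphoid lists were more negative in Cx28, by -1.63 for B cells, -1.05 for T and NK cells and -0.41 for lymph node stroma. Fat metabolism lists were also more negative there, at -0.68 for lipogenesis, -0.62 for cholesterol synthesis, -0.41 for lipolysis and -0.29 for triglyceride synthesis and fatty acid uptake. Interferon response stood at -0.22, endothelial cells at -0.21, cell cycle at -0.14 and MVB and endosomal sorting machinery at -0.12. More positive in Cx28 were skeletal muscle at 1.04, immediate early genes at 0.62, macrophages at 0.36, extracellular matrix at 0.32, adipose progenitors at 0.26 and lysosome at 0.20.

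Samples far from the other 3 of their group were sought in 250 groups, and 17 were found; chance flags about 5% of groups. The figure given is the gap to the nearest sample as a share of the group's range. Among lists, knockout 3 stood high for thyroid hormone responsive genes (0.97), knockout 4 high for insulin signalling (0.94) and interferon response (0.90), control 1 high for epithelium and mammary duct (0.86) and control 4 high for MVB and endosomal sorting machinery (0.84). Among genes, knockout 3 stood low for Epg5 (0.92), Cebpa (0.84), Igk-V21 (0.83) and Apcdd1 (0.83), and high for Ucp1 (0.91) and Ndufa6 (0.85). Knockout 1 stood high for Dact1 (0.90) and Mmp14 (0.88), and knockout 2 low for Icam1 (0.83). Control 4 stood high for Syt12 (0.90) and Axin2 (0.84), and control 1 high for Ndufa6 (0.85).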

How the results depend on the processing

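The settings with list means as covariates and without controls 1, 2 and 4 were chosen after the data were seen. Trp53inp2 kept its direction in all 18 settings, at -1.29 to -0.93, with limma's adjusted p at 0.053 to 0.98; its single probe set left the planned comparison of probe sets without a value. The number of genes past the threshold was 0 except without control 3 (42, where leaving out the others gave 0), without controls 1, 2 and 4 (9, of which 8, hair genes such as Tchh and Krt71 among them (chosen after their values were seen), are highest in the lone control 3) and with the unadjusted 1.5-fold threshold (822). The number at an unadjusted p under 0.05 was 2067 in the upper 50% of genes, where fewer genes were tested, 1271 with the litter block, 1046 in the 2 mixed litters, 901 with the B cell covariate, 810 with B cell and muscle covariates and 1320 without controls 1, 2 and 4. It ranged from 1698 (without control 2) to 4356 (without control 3) when 1 array was left out, and was 1983 without control 1, 2014 without knockout 2 and 2202 without knockout 3. The number of lists was 0 with an estimated correlation and 0 with fry, 9 with the B cell covariate, 10 without controls 1, 2 and 4, and 11 to 18 when 1 array was left out. Of 831 values of single lists under alternatives, 687 kept their side of the threshold and direction, 80 lost and 43 gained a call, and 21 reversed.

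Reversed list means were as follows. With the B cell covariate they were -0.21 for Wnt components, 0.14 for ribosome biogenesis, 0.0904 for interferon response, 0.0283 for T and NK cells, 0.0381 for lymph node stroma, 0.0973 for cell cycle and 0.0216 for circadian clock, the last by direction of the test alone. With B cell and muscle covariates they were -0.22, 0.15, 0.0906, 0.0174, 0.0259 and 0.0718 for the first 6 of these. Without controls 1, 2 and 4 they were -0.20 for Wnt components, 0.16 for ribosome biogenesis, 0.16 for interferon response, 0.0130 for cell cycle and 0.12 for skeletal muscle, the last by direction of the test alone. The litter block and the 2 mixed litters gave 0.0333 for ribosome biogenesis, and the 2 mixed litters -0.12 for neutrophils and mast cells, again by direction of the test alone. The cause was not tested. RMA values carry no measure of signal over background, so dim genes have no stated limit.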

Other observations

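The genes in the first 2 paragraphs were chosen after their values were seen, except Ucp1, Cox8b, Dsp, Tnnc1, Myh2 and Trp53inp2, and the tests in the last 2 paragraphs were also chosen after the result was seen. Muscle genes differed in which knockouts were high. Myl2, the slow and cardiac myosin light chain, stood at 8.62 in knockout 1, 7.25 in knockout 2 and 8.67 in knockout 4, but at 5.44 in knockout 3, within the control values of 5.28 to 5.55. Tnnc1 was likewise high in knockouts 1, 2 and 4, at 8.87, 7.07 and 8.83, and low in knockout 3, at 5.71, against 5.32 to 6.00 in controls. Myh2 was also lowest of the knockouts in knockout 3, at 10.24 against 10.79 to 11.52, though above the controls at 8.47 to 9.47. The muscle creatine kinase gene Ckm, by contrast, was highest in knockout 3 at 12.64 and stood at 12.19 in control 3, 9.85 in control 1 and 10.43 in control 2. Skin transcripts appeared in controls 1 and 3. Control 1 held Krt14 at 8.91, where the other arrays had 4.71 to 4.85, and Dsp at 10.65. Dsp was also raised in control 3, at 6.49, against 4.11 to 4.47 in the other 6. Control 3 held the hair follicle genes Tchh at 6.68 and Krt71 at 6.76, against 3.58 to 3.69 and 5.21 to 5.34 elsewhere.

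Ucp1 fell into high and low arrays within each genotype. It stood at 8.48, 9.61 and 9.16 in controls 1, 2 and 4 and at 6.13 in control 3, and at 10.31 in knockout 3 and 6.51, 6.52 and 6.15 in knockouts 1, 2 and 4. Cidea, another gene of brown and beige fat cells, was highest in the same arrays, at 10.27, 10.13, 10.25 and 10.39, against 8.69 to 9.30 in the others. Cox8b was too, at 11.96 to 12.15 against 11.08 to 11.61. Cox7a1, Elovl3 and Dio2 from the same list did not follow. Cox7a1 stood at 9.52 in control 1 and 10.3 in knockout 2, and Dio2 at 5.1 and 5.4. Elovl3 was flat, at 4.26 to 4.49. With litter as a block, the potassium channel gene Kcnj14, at -0.83 (SE 0.074), shared limma's smallest adjusted p, 0.18, with Trp53inp2.

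A hypothesis of less stroma in knockouts was set against the macrophage, extracellular matrix and adipose progenitor lists, which were lower within both litters that hold both genotypes. Each of the 3 mice of a litter in turn was taken as its control, giving 9 arrangements, and the mean difference of the 3 lists was as low in 1 of 9, the real one. These lists were picked because they were lower in both litters, so this restates the choice and decides nothing; the hypothesis stays open.

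A shared effect of genotype over all genes might make the differences within the 2 litters correlate across genes more in the real arrangement than in the others. The correlation was 0.157 in the real arrangement, and 4 of 9 arrangements, the real one included, gave one as high, with 0.497 as the highest. Genes are not independent replicates, and a genome-wide shared effect was not detectable in this design.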
